A study of Drosophila melanogaster with 2 samples.

How the data were processed

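Peak lists were analysed from 1 ChIP-seq group of 2 biological replicates of whole Drosophila melanogaster embryos 0 to 24 h old, which expressed CG14441 fused to eGFP. Per the labels, chromatin was sonicated, the fragment range was 200 to 800 bp, and the antibody was directed against GFP. The authors' lists were derived from the alignments of the replicates and a control alignment on the assembly dm6. The control and the alignments were not analysed here. The aligner, the peak caller and their versions are not given in the sources used here.

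There were 8 deposited peak lists: for each replicate and, in 2 versions, for the whole series, a list of ranked candidates and a thresholded list made with the irreproducible discovery rate (IDR). The deposited signal is the value of the authors' peak caller, in a unit whose scale is not stated. It is used here for ranks and for comparisons within a list. The deposited summit column, of unit other, is a distance in bp from the peak start. The deposited IDR columns are -log10 values of the global IDR. Every thresholded peak had a global IDR of 0.01 or below in its ranked list. In the ranked series list, 2 deposited signal columns give the replicates without their numbers, so they are called the first and the second replicate column, and a mean ± SD with n = 2 is over these. The lists hold no read counts, so the depth is unknown, and no limits that need a depth are given. Exact intervals are Clopper-Pearson intervals at 95%, cover counting error alone, and treat peaks or genes as independent.

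The conservative thresholded series set was the main set, and analyses used its peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X. Coordinates are 1-based. Chromosome lengths and sequence came from the dm6 reference genome, and genes from Ensembl release 115 (BDGP annotation 6.54). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

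No paired analysis was possible because there is 1 group. Replicates were compared by overlap of at least 1 bp, against 1000 random placements within arms. On simulated data with 3000 peaks of which 70.4% were kept, this measure gave 71.5%. A summit within 500 bp of a protein-coding TSS was a promoter summit. The remaining summits were classed as 5' UTR, coding exon, 3' UTR, intron or outside protein-coding genes, in that order. Tests against random placement were one-sided. When peaks were planted at TSSs among 3000 simulated peaks, the share recovered beyond chance was 40.8%, and without planted peaks 35.0% of placements reached the simulated share. Arms were tested with a two-sided exact binomial test and signals with a two-sided permutation test of the medians (100000 resamples). Adjusted p are Benjamini-Hochberg values, over the 6 arms, 37 gene lists, 25 motifs or 8192 sequences of 7 bases, with a threshold of 0.05.

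Gene lists were tested with a two-sided Fisher's exact test of genes with a main-set summit within 500 bp of any TSS, against other protein-coding genes, or for RNA gene lists against genes of any type. Of 361 symbols in the lists written by symbol, 2 distinct symbols were not matched to the annotation and are not analysed here. With 13945 genes, a planted list was called in a simulation and 0 of 200 random lists were. Motifs, as consensus sequences on either strand, were counted within 100 bp of the summit and in the flanks of the same peak 400 to 500 bp away. Sequences of 7 bases, joined with their reverse complements, were counted within 50 bp and in flanks 400 to 450 bp away. Both used a two-sided exact McNemar test, and ratios have 0.5 added to both counts. A sequence planted in a part of 1765 simulated peaks took rank 1, against flanks and also against windows of equal GC. These simulated peaks lay at random positions, without the A/T-rich core of the real summits.

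The lists, the motifs and the tests, except those named last here, were fixed before the data were examined. The same holds for the rule for what is named: CG14441; the 25 main-set peaks of highest signal found in both replicates with a protein-coding TSS within 500 bp, by the nearest gene; the 5 strongest other peaks; up to 4 members of each list with the strongest peak, or up to 2 without a peak where none had one; the 10 sequences of 7 bases with the smallest p; and each motif past the threshold. Alternatives planned then were the other series set; leaving out each replicate, by using the other replicate's own set; a stricter threshold; promoter windows of 250 and 1000 bp; TSSs of all gene types; candidates as the background; overlap of at least 50% of both peaks, summits within 100 bp and the 500 strongest peaks; the TSS share as the expectation for arms; 1 TSS per gene; motif windows of 50 bp, a control 1 kb away and a control matched on distance to TSSs; and windows of 100 bp or sequences of 6 and 8 bases. The planned IDR of 0.01 removed no peak, since it was already the threshold, so the planned fallback by signal was used. Not among the planned tests were motifs by class of peak, promoter share and GC content by peak strength, and genes by upstream GC content. The same holds for peak density in windows, summits per gene and the overlap of left-out peaks with the thresholded lists. Chosen after seeing the data were an IDR of 0.001, adding back peaks left out of the thresholded lists, transposable elements out of the background, 1 peak per run of overlapping peaks, windows of equal GC 1 to 5 kb away (the closest of 50 draws; the mean difference of summit minus window was -0.220 points), the TSS-matched control for sequences of 7 bases, the pooled abundant genes and the gene sets matched on TSS number as controls, the sequences carried from chromosome 2 to 3 and X, and the GC profiles.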

Results

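CG14441 is an uncharacterised protein-coding gene on the X chromosome of Drosophila melanogaster. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody against GFP on whole embryos, collected 0 to 24 h after egg laying, that carried a CG14441-eGFP fusion. There was 1 group of 2 biological replicates and no second condition, so the comparisons set the replicates beside each other and the peaks beside the genome. The main set, the stricter of the 2 deposited sets for the whole series, held 5116 peaks, of which 5115 lay on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X of the dm6 assembly. The sets of the single replicates held 3782 peaks (replicate 1) and 3940 peaks (replicate 2). The most common peak width in the main set was 324 bp, shared by 76.7% of its peaks, and the median signal was 116. The lists hold no read counts, so the sequencing depth behind each value is unknown.

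The first comparison asked how far the 2 replicates gave the same sites. The strongest sites recurred: of the 500 strongest peaks of replicate 1, 499 overlapped a peak of replicate 2, and of the 500 strongest of replicate 2, 497 overlapped a peak of replicate 1. Among the 25 strongest promoter peaks, those of Ugalt, CG14100 and mRpL41 came first in both replicate columns. Over all thresholded peaks on the arms, 2822 of 3768 peaks of replicate 1 (74.9%, exact 95% interval 73.5 to 76.3) overlapped a peak of replicate 2 by at least 1 bp. In the other direction 2831 of 3939 did (71.9%, 70.4 to 73.3). Random placement of the replicate 1 peaks within their arms gave a mean overlap of 1.66% and at most 2.23% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Across the 2822 shared peaks the signals of the replicates had a Spearman rho of 0.842 and a Pearson r of 0.828 on the log2 scale. These correlations are across peaks, which are not independent replicates, so no p is given. In the main set, 2834 peaks (55.4%) overlapped a thresholded peak of both replicates, 626 of replicate 1 alone and 582 of replicate 2 alone, and 1073 (21.0%) overlapped neither.

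**Figure D1:**
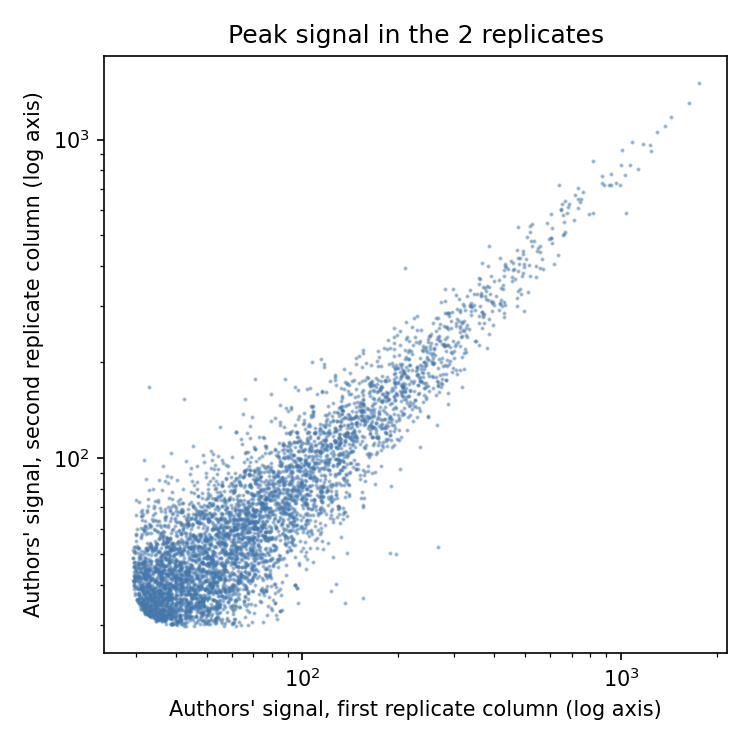
Each point is 1 of the 5115 main-set peaks on the 6 arms, with the authors' signal in the first replicate column on the horizontal axis and in the second on the vertical axis, both logarithmic. The peaks follow the diagonal (Spearman rho 0.807 over all of them). They were kept by a threshold on the IDR, into which the same columns were entered, so their agreement is partly set by this selection. The rho therefore cannot show how well the replicates agree over all candidates. Overlapping peaks are drawn as separate points.

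The second comparison asked where in the genome the tagged protein was found. CG14441-eGFP peaks lay mostly just upstream of genes or in introns, and were scarce in exons. The summits of 2141 of the 5115 peaks (41.9%, exact 95% interval 40.5 to 43.2) lay within 500 bp of a transcription start site (TSS) of a protein-coding gene, against a mean of 11.5% at random (3.65 times as many; one-sided permutation p = 0.001, the smallest possible). The share was 44.5% in the set of replicate 1 and 44.1% in that of replicate 2. Of these promoter summits, 1697 (79.3%) were upstream of the nearest TSS, at a median position of -98 bp, and 768 (35.9%) lay 50 to 150 bp upstream. Among 116197 weaker candidate peaks that did not pass the threshold, 13.6% were at promoters (odds ratio 4.56 for the main set). Coding exons held 46 summits (0.899% against 13.9% at random) and 3' UTRs held 45 (0.880% against 4.54%), each below every random placement (one-sided permutation p = 0.001). There were 22 summits in 5' UTRs beyond the promoter window (0.430% against 0.797%, one-sided permutation p = 0.00200), a call lost in the other series set (ratio 0.777, one-sided permutation p = 0.0619) and in the set of replicate 2 alone (0.735, p = 0.0719). Introns held 2038 summits, 39.8% against 39.4% at random (one-sided permutation p = 0.279). Promoters were assigned first and took 41.9% of summits but 11.5% of random positions, which lowers the share left for every later class. Whether introns were favoured among the remaining summits was therefore not tested. Sequence outside protein-coding genes held 823 (16.1% against 29.9%, one-sided permutation p = 0.001).

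**Figure D2:**
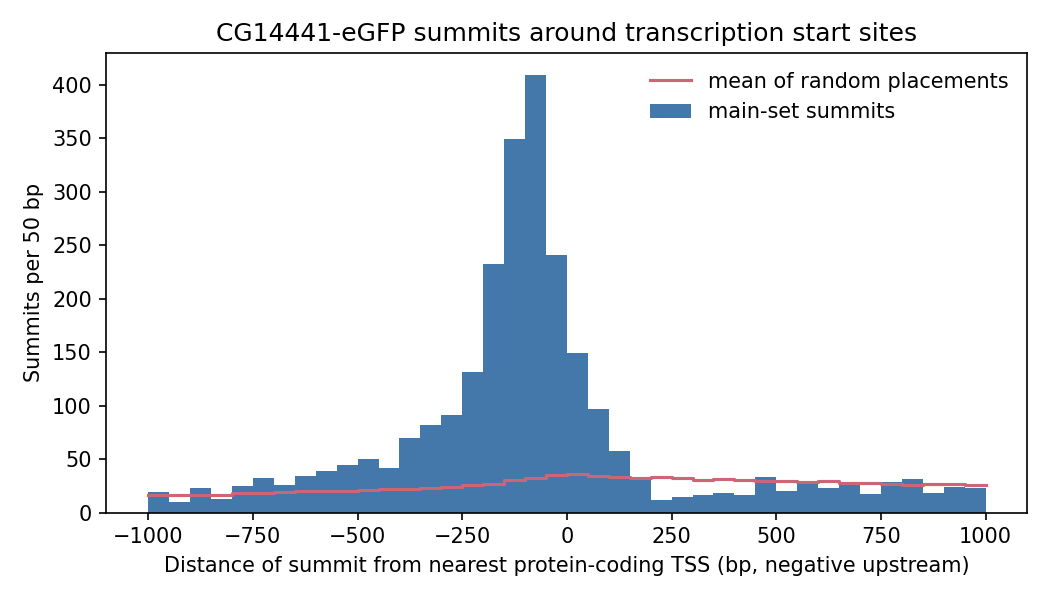
Bars give the number of main-set summits per 50 bp by their distance from the nearest protein-coding TSS, negative upstream, and the line gives the mean of random placements. The summits pile up just upstream of the TSS, with a median of -98 bp among those within 500 bp.

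The peak of highest signal in the main set was at Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, at X:2703709-2704062. Its summit lay 41 bp upstream of the TSS (-41), its signal was 3245, and the signals of the replicates averaged 1633 ± 178 (SD, n = 2). CG14100 (FBgn0036889; 3L:19590456-19590772) followed with a signal of 2920 and a replicate mean of 1468 ± 228 (SD, n = 2). Next among promoter peaks came mRpL41 (FBgn0034001; 2R:15217591-15217905), a protein of the mitochondrial ribosome, with 2467 and 1237 ± 194 (SD, n = 2). The peak at eIF6 (FBgn0034915; 2R:23850262-23850554), a factor of large ribosomal subunit maturation, had a signal of 2177 and a replicate mean of 1096 ± 188 (SD, n = 2). PNPase, a polynucleotide phosphorylase, had 1932, mRpS10 had 1897, and Chro, a chromodomain protein of polytene interbands, had 1792. Others among the 25 strongest promoter peaks found in both replicates were at CG7601, Tcs5, CenG1A, GstE13, mRpL23, CG18549, CG5611, Atat, CG8320, Lamtor3, CG13390, CG3552, Mnat9, Elp5, tank, CG1888, CG8360 and Rtnl1. The 25 ranged in signal from 1286 to 3245, and 18 of their summits were upstream of the TSS. Their replicate SD was at most 39.1% of the mean, with a median of 12.8%. For 16 of the 25, a second gene had a TSS within 500 bp of the summit, such as mRpS23 beside CenG1A and CHMP2B beside Tcs5, so the gene named is the nearest one.

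Away from promoters, the strongest peak of the main set (2L:6612556-6612882) lay in an intron of CG11050, 1025 bp downstream of a TSS, with a signal of 2620 and a replicate mean of 1310 ± 184 (SD, n = 2). The next was in an intron of ph-p, a Polycomb group gene, at X:2137200-2137506, with a signal of 2123 and a replicate mean of 1069 ± 142 (SD, n = 2). Its summit was upstream of the nearest TSS (-509 bp), just beyond the promoter window of 500 bp. Intronic peaks also stood in Adf1, which encodes a transcription factor (signal 1880, 781 bp downstream of a TSS), and in CG32772 (signal 1739, 1252 bp downstream). The peak at 2R:13035184-13035479 (signal 1821) lay outside protein-coding genes, 11913 bp from the TSS of CG13323. Promoter peaks had a higher median signal (130; quartiles 87.9 and 233; 2141 peaks) than the 2974 other peaks (108; quartiles 80.1 and 173). The ratio of the medians was 1.21 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The promoter share was 60.7% among the 511 strongest peaks and 35.4% among the 512 weakest, which include peaks that overlap stronger ones.

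Across the chromosome arms, the X carried more peaks than its length predicts and chromosome 4 almost none. The X held 1002 peaks, or 19.6% of the peaks on 17.6% of the sequence (ratio 1.12, two-sided exact binomial test, adjusted exact p = 5.32e-04 over the 6 arms). Against its share of protein-coding TSSs the ratio was 1.15 (adjusted exact p = 4.27e-06). In the set of replicate 2 alone the ratio to length was 1.06 (adjusted exact p = 0.118), and in that of replicate 1 alone 1.17 (adjusted exact p = 9.07e-06). Chromosome 4 held 2 peaks, a ratio of 0.0393 (adjusted exact p = 8.25e-19). They were at the promoters of PlexA, a semaphorin receptor (4:1027178-1027398, signal 551), and gw (4:659910-660233, signal 146), which were named after their values were seen. Replicate 2 alone had 12 peaks on chromosome 4 (ratio 0.306, adjusted exact p = 4.46e-06). The arms 2L, 2R, 3L and 3R had ratios to length between 0.947 and 1.03, with adjusted exact p of 0.132 and above, but in the set of replicate 2 alone 3R was low (0.923, adjusted exact p = 0.0193; against TSSs 0.938, adjusted exact p = 0.0355). The main set lacked 119 ranked peaks that passed the IDR threshold, 82 of them on 3R and 0 on the X. The set of replicate 2 lacked 109, whose arms are not given here. The low 3R is therefore not separated from this loss, which also raises the share of the X. Against TSSs, 2R was lower (ratio 0.875, adjusted exact p = 8.71e-06) and 3L higher (ratio 1.10, adjusted exact p = 0.00123), while 2L (0.958, adjusted exact p = 0.183) and 3R (0.983) did not pass.

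The next comparison asked which groups of genes carried a peak at a TSS. Among the lists, genes of the cytoplasmic ribosome and of insulator proteins did so most often, and genes of sensory receptors and cuticle proteins almost never. Of 13945 protein-coding genes, 2637 (18.9%) had a main-set summit within 500 bp of a TSS. Among cytoplasmic ribosomal protein genes, 54 of 93 did (58.1%, exact 95% interval 47.4 to 68.2; odds ratio 6.04, two-sided Fisher's exact test, adjusted exact p = 1.97e-15 over 37 lists). Their strongest peaks were at RpL17 (signal 507), RpS27 (475), RpL34b (460) and RpL7 (406). Pooled genes of oxidative phosphorylation, the proteasome, translation factors, tubulins and actins, a control chosen after seeing the data, had an odds ratio of 1.01 (exact 95% interval 0.690 to 1.44). In 10000 random gene sets with the same numbers of TSSs as the ribosomal protein genes, also chosen after seeing the data, at most 35 genes had a peak. Among genes of insulator and architectural proteins, 9 of 18 had a peak (odds ratio 4.30, adjusted exact p = 0.0131), led by Chro, Cp190 (signal 454), Trl, which encodes the GAGA factor (324), and BEAF-32 (199). With a window of 1000 bp the adjusted p of this list was 0.0562. Among mitochondrial ribosomal protein genes, 23 of 73 had a peak (31.5%, odds ratio 1.98, adjusted exact p = 0.0410), and mRpL41, mRpS23, mRpS10 and mRpL23 were the strongest, with signals from 1679 to 2467. That call was lost at an IDR of 0.001, with windows of 250 and 1000 bp and among genes with a candidate peak (odds ratios 1.71 to 2.01). Among germline and piRNA genes, 7 of 15 had a peak (odds ratio 3.76, adjusted exact p = 0.0492), including orb (signal 343), cuff (241), bgcn (226) and vas (93.9). This call was lost in the set of either replicate alone (adjusted exact p of 0.459 and 0.520), and also in most other alternatives.

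Peaks were fewer than among other genes at 6 lists. Of 119 odorant and gustatory receptor genes, Gr21a alone had a peak (signal 77.9; odds ratio 0.0360, adjusted exact p = 1.49e-08). None of 94 cuticular protein genes had one, Acp65Aa and Ccp84Aa among them (adjusted exact p = 4.66e-08; the exact 95% interval reaches 3.85%). Of 85 ionotropic and neurotransmitter receptor genes, Ir60e alone had a peak (signal 72.3; odds ratio 0.0507, adjusted exact p = 3.82e-06). Of 115 histone genes, His2Av, which lies outside the repeated histone cluster, alone had one (signal 223; odds ratio 0.0373, adjusted exact p = 2.45e-08). Only 4 histone genes had a candidate peak of any strength, and among genes with a candidate the odds ratio was 1.04 (adjusted exact p = 1). Of 290 tRNA genes, 17 had a peak (5.86% against 12.3% of other genes of any type; odds ratio 0.445, adjusted exact p = 0.00249), and of 269 snoRNA genes, 16 did (5.95%; odds ratio 0.452, adjusted exact p = 0.00506). The strongest peak counted for tRNA:Phe-GAA-1-2 and snoRNA:Psi28S-1232 was the one at RpL17. With a window of 1000 bp, the odds ratios were 0.775 for tRNA genes (adjusted exact p = 0.418) and 1.22 for snoRNA genes (adjusted exact p = 0.469). The tRNA call was also lost in the set of replicate 2 alone (adjusted exact p = 0.0713), and the snoRNA call among the 2558 strongest peaks.

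**Figure D3:**
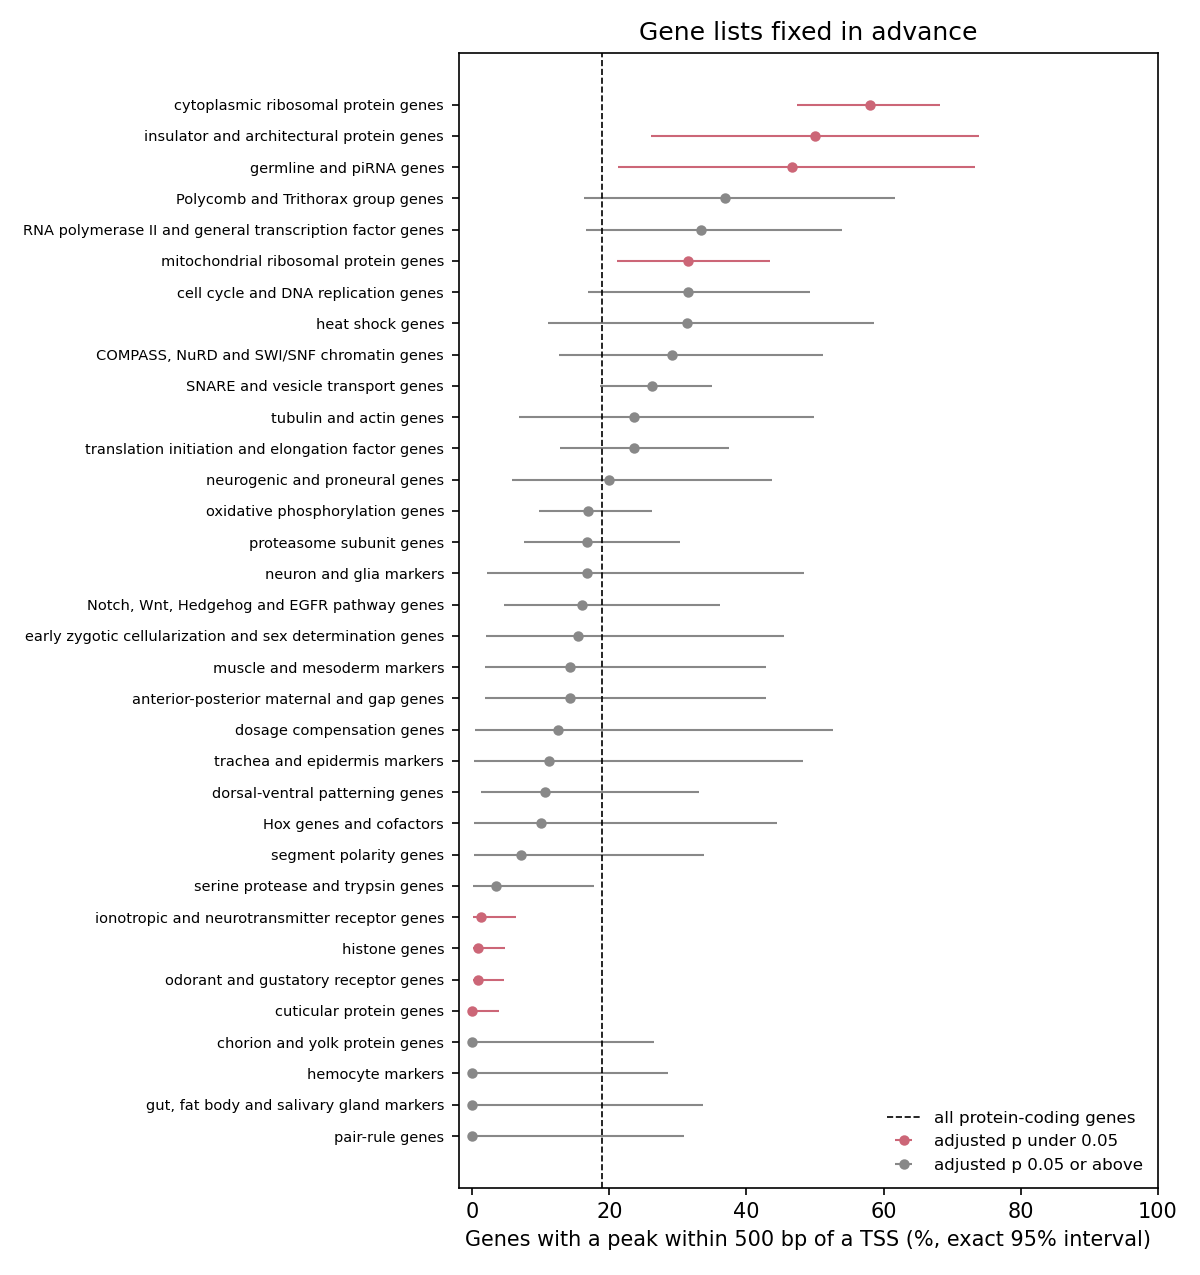
Points give the percentage of each list's genes with a main-set summit within 500 bp of a TSS, lines the exact 95% interval, and the dashed line the 18.9% of all protein-coding genes. Red lists passed an adjusted p of 0.05, with cytoplasmic ribosomal protein genes highest at 58.1%; the 3 lists of RNA genes are not drawn.

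The other 27 lists did not pass an adjusted p of 0.05 in the main set. Among chromatin and transcription genes, 7 of 19 Polycomb and Trithorax group genes had a peak (adjusted exact p = 0.197), including brm (signal 1152), ph-p (719), E(z) (445) and Su(z)12 (184). So did 9 of 27 RNA polymerase II and general transcription factor genes, such as TfIIA-L (414) and Taf5 (395; adjusted exact p = 0.197), and 7 of 24 COMPASS, NuRD and SWI/SNF genes, such as brm and Rbbp5 (179; adjusted exact p = 0.417). The dosage compensation list had a peak at JIL-1 alone of 8 genes (190; adjusted exact p = 1). Among housekeeping lists, 32 of 122 SNARE and vesicle transport genes had a peak (26.2%, adjusted exact p = 0.146), for example Vha100-2 (421), as did 11 of 35 cell cycle and DNA replication genes, for example Dp (445; adjusted exact p = 0.197). There were 12 of 51 translation factor genes (eIF6 and eEF1gamma, 371; adjusted exact p = 0.601), 15 of 89 oxidative phosphorylation genes (ND-ASHI, 1073; adjusted exact p = 0.924) and 8 of 48 proteasome genes (Rpn3, 270; adjusted exact p = 1). Of 17 tubulin and actin genes, 4 had a peak: gammaTub23C (217), alphaTub84B, betaTub97EF and betaTub56D (adjusted exact p = 0.793). Of 16 heat shock genes, 5 did: Hsp27 (1012), Hsc70-4 (272), Hsp83, Hsp26 and Hsp22, the last named after its value was seen (adjusted exact p = 0.417). Of 32 snRNA genes, 6 did, led by snRNA:U5:35D (138; adjusted exact p = 0.459). In the serine protease and trypsin list SP2353 alone of 29 genes did (69.9; adjusted exact p = 0.103). Members of that list were taken by a pattern of their symbols, so whether SP2353 encodes a protease was not checked.

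None of the lists of embryonic patterning, signalling and tissue identity genes differed from other genes past the threshold. There was no peak at any of 10 pair-rule genes, such as eve and ftz (adjusted exact p = 0.417), 9 gut, fat body and salivary gland markers, such as GATAe and srp (adjusted exact p = 0.417), 11 hemocyte markers, such as Hml and Pxn (adjusted exact p = 0.418), or 12 chorion and yolk protein genes, such as Cp7Fa and Cp7Fb (adjusted exact p = 0.323). Of 14 maternal and gap genes, bcd (178) and cad (127) had a peak (adjusted exact p = 1). So did nkd (236) of 14 segment polarity genes (adjusted exact p = 0.758), Antp (78.9) of 10 Hox genes and cofactors (adjusted exact p = 0.924), and cact (281) and dl (77.7) of 19 dorsal-ventral patterning genes (adjusted exact p = 0.793). The 4 of 20 neurogenic and proneural genes were E(spl)m3-HLH (157), pros (74.6), E(spl)m7-HLH and N (adjusted exact p = 0.997). The 4 of 25 Notch, Wnt, Hedgehog and EGFR pathway genes were spi (447), aos (141), Wnt6 and N (adjusted exact p = 1). Stronger peaks stood at moody (930), a glial receptor gene, and elav (709), a neuronal RNA-binding protein gene, the pair among 12 neuron and glia markers (adjusted exact p = 1). In the muscle and mesoderm list tin (563) and Mef2 (97.5) of 14 genes had a peak (adjusted exact p = 1), and in the trachea and epidermis list trh (134) of 9 (adjusted exact p = 1). Sxl (168) and fru (85.4) were those of 13 early zygotic and sex determination genes (adjusted exact p = 1). In the sets of the single replicates such small counts moved: neither had a peak at a neurogenic and proneural, Hox or odorant and gustatory receptor gene, and the trachea and epidermis list had 0 in replicate 1 and 4 in replicate 2.

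The last comparisons asked which sequences marked the summits. Of 25 motifs, 10 were more frequent within 100 bp of summits than in the flanks of the same peaks and 3 less frequent. The element bound by DREF and BEAF-32 (TATCGATA) was near 162 summits and in 35 flanks (ratio 4.58, two-sided exact McNemar test, adjusted exact p = 1.25e-19 over 25 motifs). Motif 7 of core promoters was at 295 against 104 (2.83, adjusted exact p = 4.52e-22), motif 1, bound by M1BP, at 60 against 6 (9.31, adjusted exact p = 2.27e-11), and the CTCF core at 117 against 40 (2.90, adjusted exact p = 2.82e-09). Motifs were also split by class of peak, which was not planned. At the 2141 promoter peaks the DREF element was near 154 summits and in 22 flanks, and at the 2974 other peaks near 8 and in 13, where it did not pass (adjusted exact p = 0.639). Motif 7 likewise was at 238 against 54 at promoters and at 57 against 50 elsewhere (1.14, adjusted exact p = 0.730), and the BEAF-32 core CGATA had ratios of 1.54 and 0.951. For motif 1 (5 against 0 elsewhere) and the Su(Hw) core (79 against 52, 1.51) the call was lost at the other peaks while the direction stayed, and no difference between the classes was tested. The CTCF core was enriched in both classes, 39 against 19 at promoters (adjusted exact p = 0.0255) and 78 against 21 elsewhere (adjusted exact p = 1.15e-07). Also more frequent were the BEAF-32 core (1.21), the homeodomain site TAATTA (1.28), the TATA box (1.52), the GATA site (1.31), the Su(Hw) core (1.62) and motif 6 (2.39). Less frequent were the E2F site (0.737), the GAGA repeat (0.744) and the E-box CACGTG (0.681). The GAGA repeat was low at the other peaks alone (85 against 166, 0.514, adjusted exact p = 2.20e-06) and not at promoter peaks (92 against 72, 1.28, adjusted exact p = 0.190), and the E-box passed in neither class. Against windows of equal GC content, a control chosen after seeing the data, the calls of the TATA box, the homeodomain, GATA and Su(Hw) sites and the E-box were lost, and the GAGA repeat (1.33) and the E2F site (1.17) turned to the other direction. Against positions at the same distance from TSSs of genes without a peak, the calls of motif 1 (1.25, adjusted exact p = 0.383), motif 6, the BEAF-32 core, the GAGA repeat and the E-box were lost, while those of the DREF element (1.47), motif 7 (2.00) and the CTCF core (4.27) passed. So did those of the homeodomain (1.31), GATA (1.35) and Su(Hw) (1.96) sites, the TATA box (1.30) and the E2F site (0.804). The E-box call was also lost in the other series set, in the set of either replicate alone (adjusted exact p of 0.0807 and 0.830) and among the 2558 strongest peaks, and the GAGA call with the control 1 kb away (adjusted exact p = 0.0937). Among the 2558 strongest peaks, at an IDR of 0.001 and within 50 bp, the calls of motif 6 and the GATA site were lost. That of motif 6 was lost in the set of replicate 2 alone too (adjusted exact p = 0.0636), and that of GATA in the set of replicate 1 alone (adjusted exact p = 0.114) and with the control 1 kb away. In the main set the other 12 motifs did not pass against flanks, among them the sites of Zelda, Twist, Bicoid, Caudal and the initiator. Some gained a call under alternatives. The Caudal site was more frequent among the 2558 strongest peaks (1.51, adjusted exact p = 0.00140), at an IDR of 0.001 (1.36) and within 50 bp (1.38). Less frequent were the Zelda site at an IDR of 0.001 (0.668, adjusted exact p = 0.0235), the Zelda (0.722) and Pho (0.712) sites in the set of replicate 2 alone, and the E-box CAGCTG within 50 bp (0.775). Against the TSS-matched positions, the Twist site was more frequent (1.35, exact McNemar test, adjusted exact p = 5.46e-04) and the STAT site less (0.764, adjusted exact p = 0.00181). With the control 1 kb away the Bicoid site was less frequent (0.833, exact McNemar test, adjusted exact p = 0.0345).

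Strong summits lay in sequence rich in A and T, and the weakest did not. The 10 sequences of 7 bases with the smallest p all consisted of A and T: TTTAAAA, TAAAATA, TATTAAA, TTAAAAA, TATTTAA, ATTTTAA, AAAATAT, ATATTAA, ATTTAAA and ATTTTTA. TTTAAAA was within 50 bp of 701 of 5115 summits and in the flanks of 288 (ratio 2.43, two-sided exact McNemar test, adjusted exact p = 6.47e-40 over 8192 sequences). Against windows of equal GC its ratio was 1.36, and of the 64 sequences of A and T alone, which all passed against flanks, 10 passed. The GC content of the 100 bp at the summit averaged 35.8% ± 10.2 (SD, 5115 peaks) against 42.9% ± 8.85 in the flanks, a measure chosen after seeing the data. The difference was -13.6 percentage points (SE 0.578) among the 511 strongest peaks, -1.82 (SE 0.673) among the 511 before the weakest, and 1.16 (SE 0.630) among the 512 weakest. Overlapping peaks were counted separately here, and merging them would leave 4929 of the 5116 peaks. The 512 weakest include peaks that overlap stronger ones, in a number not given here, so their value does not describe separate weak sites alone. It was -8.75 (SE 0.324) at promoter peaks and -5.79 (SE 0.252) at the others. It was -9.20 (SE 0.221) in the set of replicate 1 and -6.99 (SE 0.228) in that of replicate 2. Of the 2789 protein-coding genes with the lowest GC content 50 to 150 bp upstream of the TSS, 26.2% had a peak, against 14.8% of the 2789 with the highest. This split of genes was not planned.

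**Figure D4:**
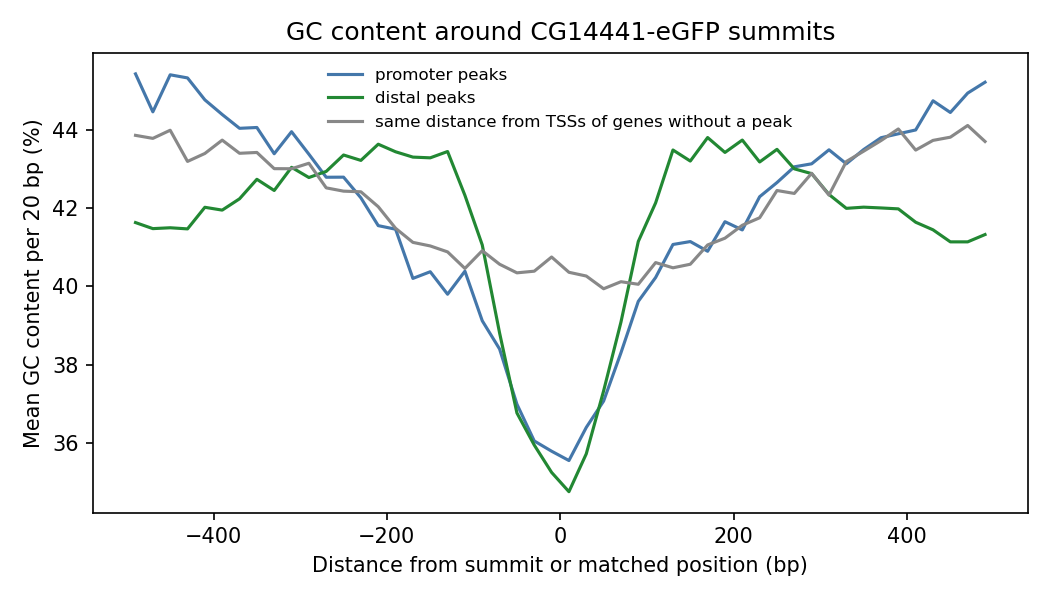
Lines give the mean GC content per 20 bp around the summits of promoter peaks and of the other peaks, and around positions at the same distance from TSSs of genes without a peak. GC content falls within about 100 bp of the summit in both classes of peaks, and by less at the matched positions, where the core is 40.4% GC on average.

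The locus of CG14441 itself (FBgn0029895; X:6699508-6719389) carried a run of peaks. Within the gene and 10 kb to either side there were 18 main-set peaks, 12 of them with a summit inside the gene. These are not all separate sites. The peaks at X:6711571-6711894 (signal 9.58) and X:6707387-6707710 (signal 7.70) overlapped stronger peaks inside the gene. The strongest, at X:6711372-6711695, had a signal of 268 and ranked 822 in the main set. The same window held 10 peaks of replicate 1, 14 of replicate 2 and 24 of the other series set. A transgene that carries the gene can itself give reads from this region, so these peaks do not separate binding from extra copies of the DNA.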

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

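In this part, the test of overlap with the thresholded lists was chosen only after the result was seen; the test of repeat sequence was not.

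Peaks with a global IDR of 0.01 or below in the ranked lists were absent from the matching thresholded lists, which is signal outside the lists the comparisons used: 105 for replicate 1, 109 for replicate 2, 119 for the main set and 138 for the other series set. Of the 119, 82 lay on 3R (68.9% against 23.2% of main-set peaks) and 26 on 2L. The strongest were upstream of cbt (2L:480924-481260; signal 2708, rank 3 of the ranked list), near Lk6 (1714), near larp (1209), at trx (1055) and near tara (806), which were named after their values were seen. Of the 119, 46 lay within 500 bp of a TSS, such as those of RpL13A (-32 bp, signal 132) and TfIIA-S (-75 bp, signal 167), also named afterwards. The gene lists left these peaks out, so a gene with no other peak was counted there as without one.

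Of the 119, 0 overlapped a peak of any thresholded list, while 74 and 87 overlapped peaks left out for replicate 1 and replicate 2; this is consistent with removal of fixed regions from every list. Repeat sequence cannot be told apart from chance by the soft-masked share around the summits, which averaged 20.1% ± 17.5 (SD), 0.0938 points above the main set (SD 14.4; two-sided permutation p = 0.945). No biological explanation was tested, since the design gives none.

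Thresholded peaks outside the 6 arms were also left unused: 14 in the set of replicate 1, 8 in the other series set, 1 in the set of replicate 2 and 1 in the main set.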

How the results depend on the processing

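Windows of equal GC and the IDR of 0.001 were alternatives chosen only after the results were seen; the other settings with values here were planned. The promoter share, the replicate overlap, the replicate correlation, the signal ratio of promoter to other peaks and the enrichment of the leading A/T sequence kept their direction, and those with a test their call, under every alternative run for them. The promoter share ranged from 33.4% (250 bp window) to 51.7% (1000 bp), and TTTAAAA had a ratio of 1.36 against windows of equal GC. The ratio to length for the X ranged from 1.06 to 1.17 when either replicate was left out, and without replicate 1 it no longer passed. Its ratio to TSSs without replicate 1 was 1.10 and still passed (two-sided exact binomial test, adjusted exact p = 0.0113). The number of peaks was 2558 for the stronger part of the set by signal and 3037 at an IDR of 0.001, by construction. The 4 enriched lists became 2 at an IDR of 0.001, 2 with a 250 bp window, 1 with a 1000 bp window and 2 among genes with a candidate peak; cytoplasmic ribosomal protein genes passed in each. With 1000 bp, the snoRNA odds ratio was 1.22, and among genes with a candidate the histone odds ratio was 1.04, where 4 histone genes were left. Against the TSS-matched control the ratios of motif 6 (0.932) and the GAGA repeat (1.12) crossed 1, but neither passed (two-sided exact McNemar test, adjusted exact p of 0.972 and 0.415). Against windows of equal GC, the GAGA repeat (1.33) and the E2F site (1.17) turned, and 5 other motifs were depleted in place of the first 3. The E-box CAGCTG gained a call there, at 486 summits against 358 windows (1.36, two-sided exact McNemar test, adjusted exact p = 2.36e-05). Against flanks its ratio was 0.933 and it did not pass. Except where the construction is named, the cause was not tested. The unknown depth limits what a missing peak can show.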

Other observations

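In this part, all tests were chosen only after the result was seen, except that of GC content at the peaks over CG14441.

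Other sequences led when the control was matched on GC. Against windows of equal GC, the leading sequences of 7 bases were ACAGTGG (170 summits against 44 windows, ratio 3.83, adjusted exact p = 9.34e-15), CACAGTG (174 against 51), CAGTGCA (184 against 73), ACTATCG (118 against 35) and CAGTGTA (116 against 36), named after their values were seen. Of the 10 sequences that led on chromosome 2 alone, 9 were also more frequent at summits on chromosomes 3 and X, ACAGTGG at 100 summits against 25 windows, although all arms had been examined before. Several of the 10 share the bases CAGTG or their reverse complement CACTG, so they are not separate findings. CAGTG was at 27.3% of the 2558 weaker summits (ratio 1.86 to windows of equal GC) and at 19.7% of the 2557 stronger (1.72). Whether CG14441 binds such sequences was not tested.

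Some genes held many summits, among them kirre (25; 15.1 expected from its length), sbb (15; 3.03), shn (12; 2.23) and CHES-1-like (12; 1.04), which were named after their values were seen.

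For the A/T-rich summits, base composition shared with promoters of genes without a peak is argued against as the whole source. The GC difference of core and flank at promoter peaks differed from that at matched positions of such genes by -5.69 percentage points (SE 0.448). Genes with and without a peak differed in kind in the lists. Composition particular to the kind of promoter that carries peaks therefore stays open. A bias of the libraries towards A/T-rich fragments predicted a core of lower GC in the weaker candidates, but their core was 4.97 points richer than their flanks. This cannot decide on such a bias, which could itself lift A/T-rich sites above the threshold and leave others below it. The control alignment, which bears on such a bias, was not analysed. Base composition as the whole source of the A/T sequences is argued against, by a small margin: in 3175 pairs of exactly equal GC, summits held 0.256 (SE 0.0855) more different sequences of A and T alone than windows, 5.31 against 5.06. Of the 64 such sequences, which all passed against flanks, 10 passed against windows of equal GC. No biological explanation was tested, so a preference of CG14441 for A/T-rich sequence remains a hypothesis, found on the same data.

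The run of peaks over CG14441 was weighed as well. Overlapping peaks were counted separately in every window. The window of 39882 bp held 18 summits, while 3352 other windows of that size held 1.52 ± 1.93 (SD) and at most 14, so 0% of them reached it and an ordinary density of peaks is argued against. Extra copies of the locus carried by the transgene stay open: the 18 peaks had a core 4.72 points richer in GC than their flanks (SE 2.80), which is in line with the weaker candidates and unlike the main set (-7.03). The window held 58 candidates of any strength, a number that 9.96% of the other windows reached. No biological explanation was tested, binding of the protein at its own gene included.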
